A study of Rattus norvegicus with 2 samples.

How the data were processed

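Per the labels, endothelial cells of the aorta and of the endocardium were taken from the same pair of rats, pooled by origin and kept apart, cultured for 2 passages under closely matched conditions, and total RNA of each was hybridised to an Affymetrix rat genome U34A array. There were 2 groups with 1 array each. The deposited values were intensities on a linear scale, 1 per probe set and array, of the kind that can fall below 0; the software that summarised probes to probe sets is not given in the sources used here. Over all 8799 probe sets the deposited intensities had a 2% trimmed mean of 2504.33 on the aortic and 2504.04 on the endocardial array, as after scaling each array to a shared target. The scanner settings of the 2 arrays had 41 fields, of which 2 differed, the fluidics module and the scan time; the arrays were of the same chip lot.

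The 59 control probe sets were left out of gene values. The 8740 others were scaled so that both arrays had the same 2% trimmed mean (factors of 1.00 for the aortic and 0.999 for the endocardial array). Values under a floor, the median of all scaled values (635.4), were set to the floor, and probe sets at or under it on both arrays were left out. Above the floor lay 4361 probe sets on the aortic and 4379 on the endocardial array; 4808 probe sets were kept, of which 3932 were above the floor on both. Across those 3932 the log2 intensities of the 2 arrays had a Pearson r of 0.927; probe sets are not independent replicates. Probe sets were paired with genes by the platform annotation, with symbols looked up by gene identifier in a RefSeq gene table of assembly GRCr8: 7006 probe sets had exactly 1 symbol, 308 had several and 1426 had none, and only the first kind was used. Of these, 6985 matched the table and 0 symbols changed. No coordinates were used. Of 4736 symbols on the array, 2935 were measured. The value of a gene was the median log2 ratio, endocardial over aortic, over its kept probe sets, and its intensity was their median intensity; 798 genes had several kept probe sets. Where the dimmer array was at or under the floor, or a probe set at or under it could move the median of its gene, the fold is given as a lower bound, taken against the floor; for the genes with the largest differences, bounds are taken against the highest background control, a choice made after the data were examined.

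With 1 array per group no test across samples was possible and no p-value is given. Genes were counted at a fixed 2-fold difference, and at 4-fold. Gene lists, 22 in all, were fixed before the data were examined, as were the alternatives of processing and the rule for named genes. A list with at least 4 measured members was set against 10000 random lists of the same size, matched on mean expression in 10 bins, and was said to stand apart when its median lay at or under the 2.5th or at or over the 97.5th percentile; 21 lists could be ranked. The percentile describes these 2 arrays and not the 2 cell types.

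Named genes were, per direction, the 12 with the largest log2 ratio whose intensity was above the floor on both arrays and above the 75th percentile of scaled values on the brighter one, and whose kept probe sets all had the same sign; the 4 with the highest bound among genes at or under the floor on the dimmer array; the 2 highest and 2 lowest members of each list; and 23 genes named in advance, of which 1 is not reported here. The intensity of a gene with several probe sets, their median, was the value held against the floor. Other members of lists were named where a count of members past 2-fold called for an example, and genes of 3 further lists were named after their values had been seen.

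Precision was described in 3 ways. The SD of log2 ratios among probe sets of the same gene was 0.39 over 625 genes and 1432 probe sets above the floor on both arrays, 0.46 for the dimmer and 0.32 for the brighter part. The 38 background controls on the array, which are opposite-strand, bacterial, yeast and mouse control probe sets, gave 7 values above the floor on the aortic and 6 on the endocardial array, the highest 1743.4. The counting and list steps were tested on simulated data with known differences. With wide noise (log2 SD 0.39, with linear SDs of 742 and 560), 36.2% of genes made 2-fold different and 80.9% of genes made 4-fold different passed 2-fold among 3196 genes, and 269 of 3008 unchanged genes did. A narrower noise (log2 SD 0.32, linear SD 236), added after the wide one had been seen to count the noise of dim probe sets more than once, gave 38.8% and 87.8% among 2917 genes, and 45 of 2721 unchanged genes. Of 200 random lists of 15 genes with no shift added, 5% stood apart, and with a log2 shift of 0.5 added 96% did; for lists of 6 genes the shares were 3% and 53.5%, and for lists of 40 genes 6% and 100%.

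Alternatives were the deposited values without rescaling, quantile normalization, centring on the median log2 ratio, a loess of the log2 ratio on intensity (span 0.4), a floor at the 75th percentile (2576), no floor other than the 1st percentile of positive values (13.1), the brightest probe set of each gene, plain probe set types alone, thresholds of 1.5-fold and 3-fold, unmatched random lists, and lists without their farthest member. A floor at the highest background control was added after the data were examined. The 3 further lists, of macrophage, fibroblast and hypoxia-inducible glycolytic genes, were used for tests of explanations. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.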

Results

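Gene expression was compared between cultured rat endothelial cells of 2 origins, the aorta and the endocardium, which lines the chambers of the heart. Cells of each origin were taken from 2 rats, pooled and passaged 2 times, and the total RNA of each pool was read on 1 Affymetrix rat U34A array. Each group therefore had 1 array, so no difference below has a replicate check and none was tested. Each array gave an intensity for each probe set, from -22058.8 to 103931 on the aortic array and from -9718.5 to 96946.6 on the endocardial array. Values at or below 0 made up 25.8% of the aortic and 24.3% of the endocardial probe sets. Against a floor of 635.4, the median of the scaled intensities, 2935 genes were measured on at least 1 array, and ratios are given as endocardial over aortic.

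The comparison asked which transcripts differ between endothelium of the heart chambers and endothelium of the aorta under closely matched culture conditions. The endocardial array was brighter for Lyz2, the lysozyme of macrophages, at least 19.3-fold, for the actin-associated muscle protein Pdlim3, at least 13.4-fold, and for the matricellular protein Postn, 7.87-fold, where bounds are taken against the highest background control (1743.4). The aortic array was brighter for Ndufa4l2, a hypoxia-inducible mitochondrial protein, at least 15-fold, for the proteoglycan Dcn, at least 10.9-fold, and for the leukocyte adhesion receptor Vcam1, at least 11.7-fold. Macrophage and leukocyte genes were higher as a group on the endocardial array (median log2 ratio 0.84) and fibroblast genes were lower (median log2 ratio -0.38). The macrophage and leukocyte median was not apart from random lists with the floor at that control (0.29) or at the 75th percentile (0.15). At least 2-fold higher intensity on the endocardial array was found for 174 genes (5.93%) and at least 2-fold lower intensity for 122 genes (4.16%), while 2639 genes (89.9%) lay between. A difference of at least 4-fold was found for 39 genes in the higher and 18 genes in the lower direction. In simulated arrays, 1 of 3008 unchanged genes passed 4-fold with wide noise, in the higher direction, and 0 of 2721 did with narrow noise. Among simulated unchanged genes, 4.16% passed 2-fold higher and 4.79% passed 2-fold lower with a wide noise setting, and 0.81% and 0.85% did with a narrow one. The observed lower share was under the wide rate, but that setting counts the noise of dim probe sets more than once. Both observed shares were above the narrow rates. Neither setting includes differences between cultures of the same origin.

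**Figure D1:**
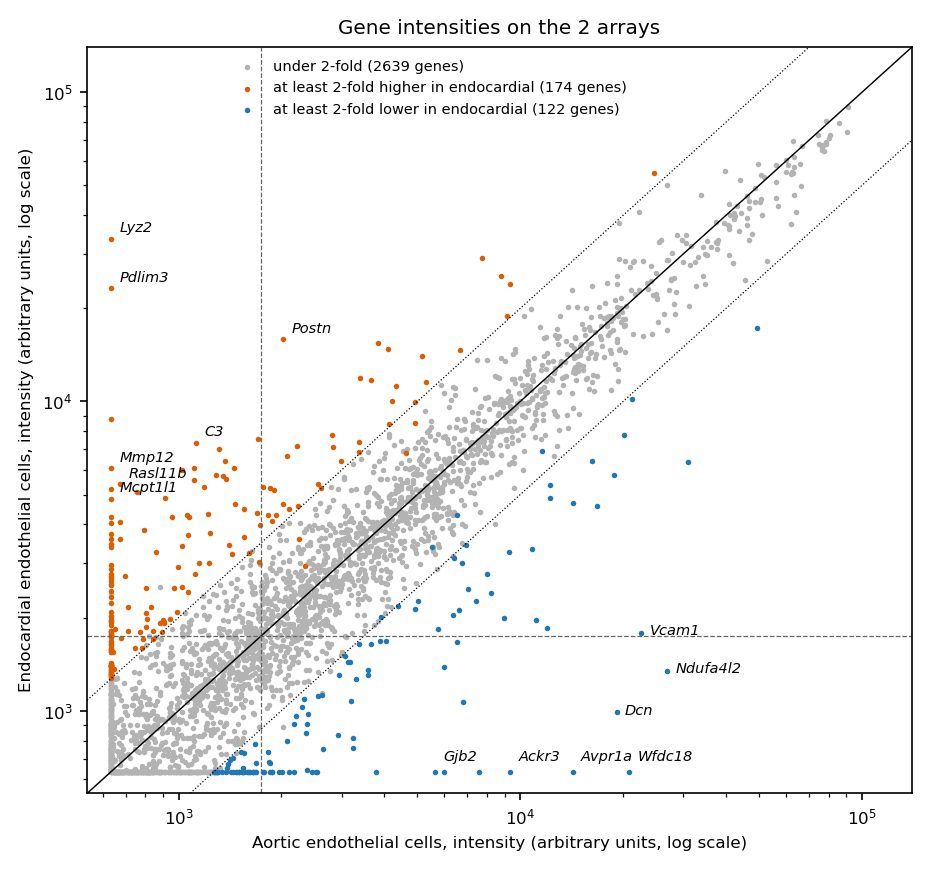
Intensity of each of the 2935 measured genes on the aortic (x axis) and endocardial (y axis) array, in arbitrary units on log axes, with values under the floor of 635.4 drawn at it. The solid line marks equal intensity, the dotted lines 2-fold differences and the dashed lines the highest background control (1743.4). Lyz2 and Pdlim3 lie at the aortic floor and far up on the endocardial axis, and Ndufa4l2, Dcn and Vcam1 lie far to the right.

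Among genes with a median intensity above the floor on both arrays, Postn was higher on the endocardial array, with an intensity of 2026 on the aortic and 15939.7 on the endocardial array. The other 11 genes named in this direction had aortic values at or under the highest background control for at least 1 probe set, so their folds are lower bounds against that control and their order is not resolved. Higher on the endocardial array were the complement component C3 (at least 4.20-fold), the secreted phosphoprotein Spp1 (at least 4.01-fold), the prohormone-processing enzyme Cpe (at least 3.68-fold) and Sod3, the extracellular superoxide dismutase (at least 3.19-fold). Natd1 (at least 3.19-fold), the small GTPase Rasl11b (at least 3.09-fold), the thioredoxin inhibitor Txnip (at least 3.01-fold) and the mitotic kinase Plk1 (at least 2.93-fold) were also higher, as were the mitochondrial beta-oxidation enzyme Echs1 (at least 2.34-fold), the iron-sulphur cluster assembly factor Mms19 (at least 2.21-fold) and the myelin-associated phosphodiesterase Cnp (at least 2.06-fold). Of genes at or under the floor on the aortic array, Lyz2 reached 33619.5 on the endocardial array and Pdlim3 reached 23283. Against the same control, the macrophage elastase Mmp12 was at least 3.49-fold higher and the mast cell protease gene Mcpt1l1 at least 2.78-fold higher. All of these genes except C3, Sod3, Rasl11b and Txnip rested on 1 kept probe set each, pairings with genes came from the platform annotation and were not checked by sequence, and the other probe set of Mms19 and of Mcpt1l1 was under the floor on both arrays.

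In the opposite direction, Ndufa4l2 had an intensity of 26926 on the aortic and 1347 on the endocardial array, with all of its 5 probe sets lower. Dcn stood at 19147 and 986.5 over 4 probe sets, and Vcam1 at 22620 and 1788 over 2 probe sets. With both values above the highest background control, the ectonucleotidase Enpp3 was 5.69-fold lower on the endocardial array, tissue factor, F3, which starts the coagulation cascade, 4.88-fold, the lactate transporter Slc16a3 4.50-fold and the transcription factor Klf4 3.64-fold. Against that control, the growth arrest and DNA damage gene Gadd45a was at least 5.36-fold lower, the secreted protein Wfdc1 at least 3.91-fold, the collagen chain Col11a1 at least 3.44-fold, and the neurotrophic factors Pspn and Ntf4 each at least 1.86-fold. Of genes at or under the floor on the endocardial array, Wfdc18 was at least 11.9-fold lower, the vasopressin receptor Avpr1a at least 8.17-fold, the chemokine-scavenging receptor Ackr3 at least 5.36-fold and the gap junction protein Gjb2 at least 3.24-fold. All of these genes except Ndufa4l2, Dcn, Vcam1, Gadd45a and Klf4 rested on 1 kept probe set each. The other probe set of Col11a1 and of Ntf4 was under the floor on both arrays. Every kept probe set value exceeded the highest background control for 4 of the 12 lower and 1 of the 12 higher genes with a median above the floor on both arrays.

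**Figure D2:**
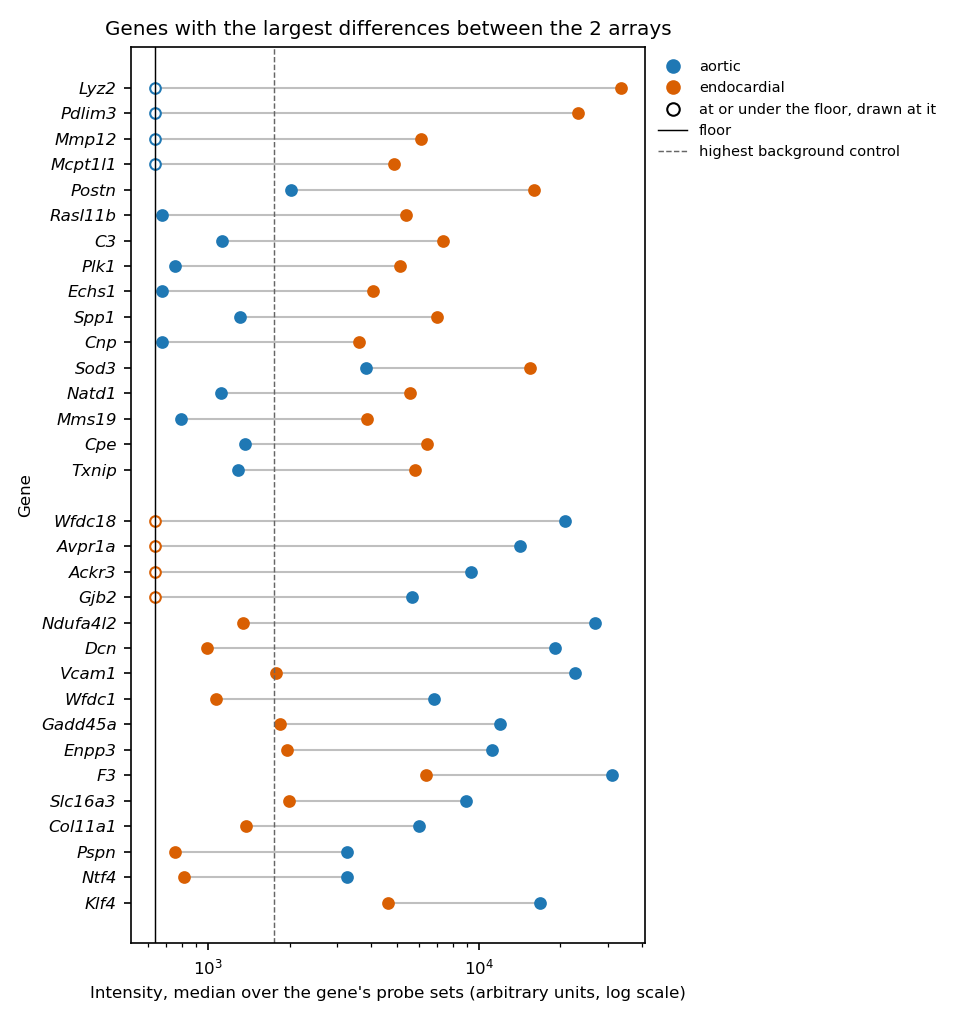
Intensity (arbitrary units, log axis) of the genes with the largest differences on the aortic (blue) and endocardial (orange) array, as the median over each gene's probe sets, with open circles for values at or under the floor. The upper block holds genes higher and the lower block genes lower on the endocardial array, from Lyz2 at the top to Klf4 (3.64-fold) at the bottom, and many of the dimmer values lie left of the dashed line of the highest background control.

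General endothelial markers went both ways. Bounds for members of gene lists are taken against the floor. A log2 ratio printed for such a member can rest on a value under the highest background control. With the floor at that control, 0 of 4 measured pan-endothelial genes passed 2-fold. Of 6 measured pan-endothelial genes, 1 was at least 2-fold higher, the transcription factor Ets1 (at least 2.22-fold, with a log2 ratio of 0.43 for 1 of its 2 probe sets and an aortic value under the floor for the other), and 1 was lower, the angiotensin-converting enzyme Ace (log2 ratio -1.16), and the list median of -0.23 lay at the 13.6th percentile of matched random lists. Nos3, the endothelial nitric oxide synthase, had a log2 ratio of -0.06, the VEGF receptor Flt1 0.35 and thrombomodulin, Thbd, -0.46. Vwf, Pecam1, Kdr and Gja4 were under the floor on both arrays, and Cdh5 and Tek had no probe set paired with that symbol alone. None of the 5 measured endocardial markers passed 2-fold (median 0.38, 89.2nd percentile). With the brightest probe set of each gene 2 were at least 2-fold higher, with plain probe sets 1, and with no floor 4 of 7. Among the 5 were Npr3 (0.02), Nrg1 (at least 1.30-fold higher, with 3 probe sets from 0.19 to at least 2.10 in log2 ratio), Bmp6 (0.43) and Gata6 (-0.55). Gata4 had 2 probe sets of opposite sign, each under the floor on 1 array. In simulated lists of 6 genes, a log2 shift of 0.5 stood apart in 53.5% of 200 lists, so a shift of that size in lists as short as these could be missed. Arterial markers were higher on the endocardial array as a list, with 4 of 11 genes at least 2-fold higher, 1 lower and a median of 0.40 at the 98.3rd percentile. That median came inside the range of random lists with the brightest probe set (0.26), with plain probe sets (0.33), without the farthest member (0.33), and with the floor at the 75th percentile (0.10) or at the highest background control (0.14). The Notch ligand Jag1 was at least 4.35-fold higher, Notch1 was at least 2.19-fold higher, and elastin, Eln, was at least 2.44-fold lower. The matrix Gla protein Mgp had a log2 ratio of 1.15. The semaphorin receptor Nrp1 had a log2 ratio of 1.23, with an aortic intensity (1550) under the highest background control. With the floor at that control, 2 of 9 measured arterial genes were at least 2-fold higher and 0 lower. The kept probe sets of Flt1, Npr3, Notch1 and Eln were under the highest background control on both arrays, so their ratios do not show equal or different expression. Nos3 exceeded it with 1 of its 4 kept probe sets, on the aortic array (1832). Nrg1, Gata4 and Ets1 exceeded it with 1 probe set each, on the endocardial array (2732, 2927 and 2324). The connexin gene Gja5 had a log2 ratio of -0.17 for 1 probe set and an aortic value under the floor for the other.

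Markers of other cell types also differed between the arrays. Of 15 measured macrophage and leukocyte genes, 6 were at least 2-fold higher on the endocardial array and 0 lower, and the median of 0.84 exceeded that of all 10000 matched random lists. All 15 were above the floor on the endocardial array and 5 on the aortic array. A member with 1 kept probe set, above the floor on the endocardial array alone, could only give a positive ratio. With the floor at the highest background control 1 of 8 measured members was at least 2-fold higher, and 1 of 7 with the floor at the 75th percentile. Besides Lyz2, and against the floor of 635.4, the lysosomal protease Ctss was at least 5.31-fold higher and the leukocyte surface protein Cd53 at least 3.16-fold. Against the same floor the MHC class II chain RT1-Da was at least 2.43-fold higher and its invariant chain Cd74 at least 2.42-fold. With the floor at the highest background control none of these genes besides Lyz2 passed 2-fold. The MHC class II chain RT1-Db1 had a log2 ratio of 0.05 and Cd14 of 0.38. No other member had median intensities above that control on both arrays. The 3 probe sets of RT1-Ba, an MHC class II chain, went both ways. The pan-leukocyte phosphatase Ptprc was under the highest background control on both arrays, as were the kept probe sets of Myh6, Nppa and Aldh1a2. Of 17 fibroblast genes, all above the floor on both arrays, 2 were at least 2-fold lower (Dcn and the collagen cross-linking enzyme Lox, log2 ratio -1.53), 1 was higher (Postn, 2.98) and 14 lay between. The fibroblast median of -0.38 was at the 0.04th percentile, and 13 of the 17 genes also stood in another list. The collagen gene Col1a1 had intensities of 74687 on the aortic and 68163 on the endocardial array. Smooth muscle genes had a median of 0.23 at the 98.0th percentile, with 2 of 13 genes at least 2-fold higher, the myosin light chain Myl9 (1.54) and the integrin Itga8 (1.21), and 1 lower, the myosin heavy chain Myh11 (at least 3.99-fold). That median came inside the range with the brightest probe set (0.15), plain probe sets (0.047), no floor (0.23) and unmatched random lists (0.23). With the floor at the highest background control, 1 of 11 measured smooth muscle genes was at least 2-fold higher and 0 lower. The aortic intensity of Itga8 (803.7) was under that control. The smooth muscle actin Acta2 had a log2 ratio of 0.71, with intensities of 26902 on the aortic and 50038.6 on the endocardial array. Tagln had a log2 ratio of 0.23, with intensities of 49583.5 and 58741.5. Acta2, Tagln and Col1a1 were thus bright on both arrays, while Vwf, Pecam1 and Kdr were under the floor on both. That the cultured cells are endothelial is taken from the labels. Of 7 cardiomyocyte genes, 0 were at least 2-fold higher and 1 lower, Myh6 (at least 2.5-fold), with Nppa at -0.18, and the list lay at the 71.2nd percentile with a median of 0.10 and a mean of -0.08, opposite in sign. The 2 measured mesothelial and epicardial genes, too few for a percentile, were Wt1 (1.09) and Aldh1a2 (at least 1.36-fold higher), with a median of 0.77. The aortic intensity of Wt1 (907.7) was under the highest background control (1743.4), and its endocardial intensity (1932.5) was near it. Wt1 rested on 1 kept probe set, and its others were under the floor on both arrays.

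**Figure D3:**
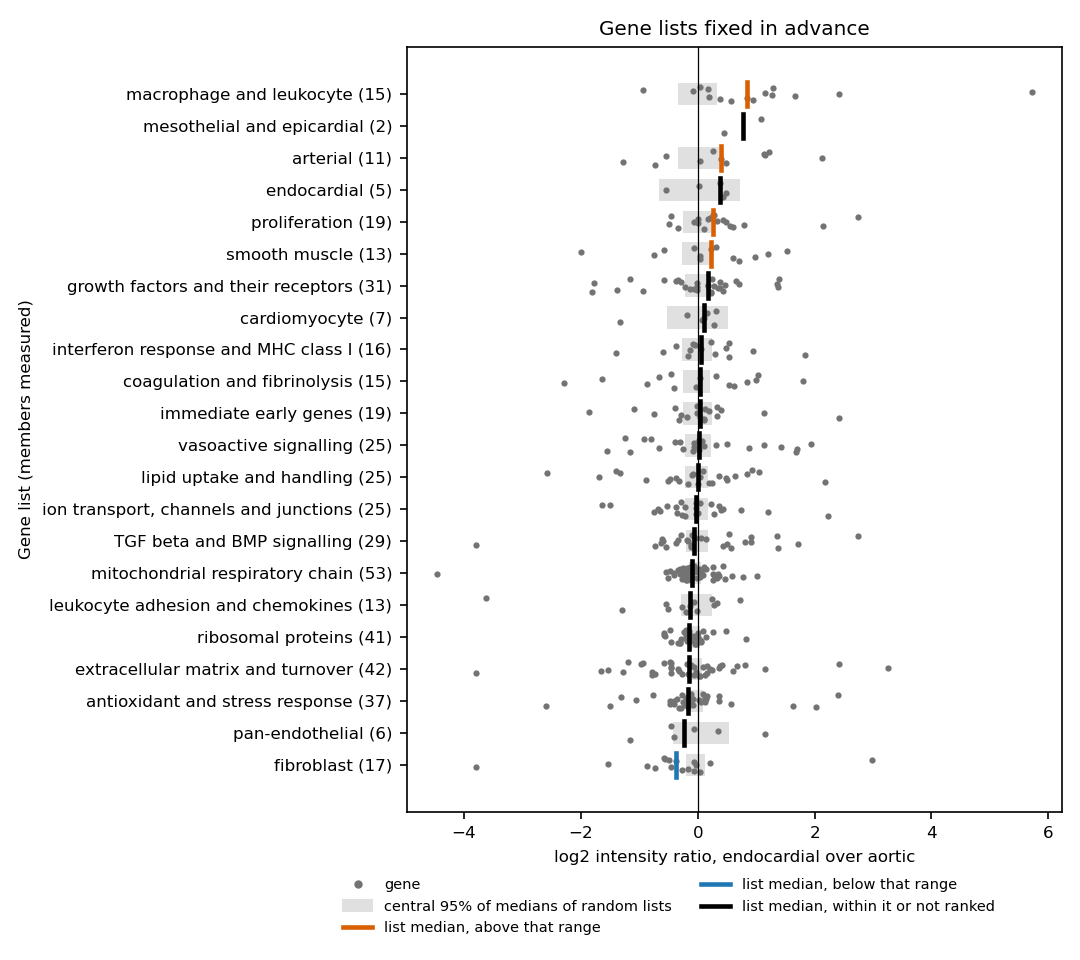
Log2 intensity ratio (endocardial over aortic, x axis) of each measured member of the 22 gene lists (y axis), with the list median as a vertical bar and the central 95% of medians of matched random lists as a grey band. The macrophage and leukocyte, arterial, smooth muscle and proliferation medians lie above their bands and the fibroblast median below its band.

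Genes of vasoactive signalling, a main function of endothelium, went both ways within their list. Of 25 measured genes, 5 were at least 2-fold higher on the endocardial array and 3 lower, with a median of 0.02 at the 57.0th percentile. The higher genes included endothelin, Edn1 (1.13, from an intensity of 1874 to 4095), adrenomedullin, Adm (1.68), the angiotensin receptor Agtr1a (1.70) and the soluble guanylate cyclase subunit Gucy1b1 (at least 3.85-fold). The lower genes were Ace, the cyclooxygenase Ptgs2 (at least 2.38-fold) and the adenosine receptor Adora2b (at least 2.95-fold). With the floor at the highest background control, 4 of 18 measured genes of this list were at least 2-fold higher and 0 lower. In the coagulation and fibrinolysis list, 2 of 15 genes were at least 2-fold higher, the tissue plasminogen activator Plat (1.81) and the tissue factor pathway inhibitor Tfpi (1.03). F3 and the urokinase receptor Plaur (at least 3.10-fold) were lower, and the list median of 0.04 at the 77.4th percentile was opposite in sign to the mean of -0.01. With the floor at the highest background control (1743.4), 2 of 11 measured genes were higher and 1 was lower, F3. The aortic intensity of Plaur, 1968, lay near that control. Of 13 leukocyte adhesion and chemokine genes, 2 were lower, Vcam1 and the chemokine Ccl20 (-1.29), and 0 were higher, with a median of -0.13 at the 22.7th percentile. With the floor at the highest background control, 1 of 9 measured genes was lower, Vcam1. The endocardial intensity of Ccl20 (976.9) was under that control. Icam1 had a log2 ratio of -0.55, the signalling factor Nfkb1 0.72, and Il1b was at least 1.25-fold higher.

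In the extracellular matrix and turnover list, 3 of 42 genes were at least 2-fold higher and 5 lower, with a median of -0.15 at the 5.87th percentile. The higher genes were Mmp12, Spp1 and Mgp, and the lower genes were Dcn, the heparan sulphate proteoglycan Gpc1 (-1.65), Lox, Eln and the proteoglycan Vcan (-1.19). In the list of TGF beta and BMP signalling, 4 of 29 genes were higher, among them the ligand Tgfb2 (at least 6.66-fold) and the activin antagonist Fst (1.72), and 1 was lower, Dcn. With the floor at the highest background control, 3 of 20 measured genes of this list were higher and 1 lower. The median of this list, -0.07 at the 33.0th percentile, and its mean, 0.12, were opposite in sign, and the receptor Acvrl1 had a log2 ratio of -0.73. Of 31 growth factors and receptors, 3 were higher, among them Tgfa (at least 2.62-fold) and Igf1 (at least 2.59-fold), and 4 lower, among them the receptor Egfr (-1.81) and the IGF-binding protein Igfbp6 (-1.77). Their median of 0.18 was at the 97.4th percentile, just inside the central 95%, and their mean was -0.01, opposite in sign. With the floor at the highest background control, 2 of 14 measured genes of this list were higher and 2 lower. The endocardial intensity of Egfr (835.4) was under that control.

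Proliferation genes were higher on the endocardial array as a list (median 0.26, 98.6th percentile), but not apart from random lists with the brightest probe set (0.12, 88.9th percentile), plain probe sets (0.17, 91.4th percentile) or the floor at the highest background control (0.24). The list had 2 of 19 genes at least 2-fold higher, Plk1 and the cyclin Ccnd2 (at least 4.42-fold), and 0 lower; Cdc20 (-0.50) and Prim1 (-0.46) were the lowest members. Of 37 antioxidant and stress response genes, 3 were higher, among them Sod3 and the ferroxidase Cp (at least 4.08-fold), and 4 lower, among them Gadd45a and the stress-induced factor Ddit3 (-1.50), with a median of -0.16 at the 3.73rd percentile. Among 19 immediate early genes, Dusp6 (at least 5.37-fold) and Jun (at least 2.19-fold) were higher and Klf4 and Myc (-1.08) lower, with a median of 0.04 at the 65.9th percentile. Among 16 genes of the interferon response and MHC class I, the interferon gamma receptor Ifngr1 (1.83) was higher and Mx2 (-1.40) lower, Psmb8 had a log2 ratio of 0.94 and Oas1a -0.60, and the median of 0.05 was at the 74.6th percentile.

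Among 25 genes of lipid uptake and handling, 2 were at least 2-fold higher, apolipoprotein E, Apoe (at least 4.55-fold), and the fatty acid transporter Slc27a1 (at least 2.07-fold), and 4 were lower, including the desaturase Scd (at least 5.97-fold) and the sterol regulator Insig1 (-1.70). Their median of -0.00 was at the 58.4th percentile. With the floor at the highest background control, 1 of 23 measured genes of this list was higher and 3 were lower. Among 25 genes of ion transport, channels and junctions, the sodium pump subunit Atp1b1 (at least 4.67-fold) and N-cadherin, Cdh2 (1.20), were higher, the glucose transporter Slc2a1 (-1.65) and the lactate transporter Slc16a1 (-1.49) were lower, and the median of -0.03 was at the 47.5th percentile. The gap junction gene Gja1 had a log2 ratio of -0.65. In the mitochondrial respiratory chain list, 51 of 53 genes lay under 2-fold; Ndufa4l2 was lower, the muscle-type oxidase subunit Cox6a2 (1.01) was higher, Cox4i2 had a log2 ratio of 0.77, and the median of -0.09 was at the 11.5th percentile. Ndufaf3 had a log2 ratio of -0.54, with probe sets from -0.61 to 0.95. Cox6a2 rested on 1 kept probe set, with an aortic value (1608) under the highest background control. Its other probe sets were below 0 on both arrays. With the floor at that control, 0 of 50 measured genes of the mitochondrial list were higher and 1 was lower. None of the 41 genes of the ribosomal protein list passed 2-fold (median -0.14, 6.66th percentile); Rps24 was lowest among its members at -0.59, Rpl5 stood at -0.57, Rps3a at 0.48 and Rpl30 at 0.82. The name pattern of this list also took in the kinase gene Rps6kb1.

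RNA quality was close on the 2 arrays. The ratio of 3' to 5' control intensity was 1.11 on the aortic and 1.09 on the endocardial array for beta-actin, 1.17 and 1.21 for Gapdh, and 1.75 and 1.69 for hexokinase. The 9 spiked bacterial controls had log2 ratios from -0.25 to 0.36, with a mean of 0.03. Across all genes the median log2 ratio was -0.02, and 5 of the 21 ranked lists lay outside the central 95% of random lists where 1.05 would by chance, although lists share members. Probe sets of the same gene disagreed with an SD of 0.39 in log2 ratio (625 genes), and 8.94% (wide noise) and 1.65% (narrow noise) of the genes left unchanged in simulated arrays passed 2-fold in either direction. With the floor raised to the highest background control the 2-fold counts were 76 higher and 45 lower, and of the 5 lists the fibroblast list alone stayed outside the range of random lists under every alternative tried. The kept probe sets of Il1b, Tgfa, Jun, Prim1, Slc27a1 and Rpl5 were also under that control on both arrays.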

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

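The floor at the highest background control was chosen after the data were examined; all other alternatives were chosen before. The counts of genes at least 2-fold higher and lower, 174 and 122, moved most with the floor and the fold: 45 and 40 with the floor at the 75th percentile, 648 and 620 with no floor, 76 and 45 with the floor at the highest background control, 385 and 329 at 1.5-fold, and 67 and 36 at 3-fold. The higher share of the calls was 58.8% in the main counts and between 57.3% and 62.6% under the 4 scaling alternatives. Under these and both probe set alternatives the counts stayed within 1.5 times the main ones. Each stricter fold or looser fold changes what is counted, and a raised floor leaves fewer genes to count (1505 and 1904 in place of 2935); without a floor, dim values near 0 give large ratios.

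Of the list medians, the fibroblast median stayed apart from random lists under all 11 alternatives, at percentiles from 0.02 to 0.26, and its value lay between -0.45 and -0.32. The macrophage and leukocyte median came inside the range with the floor at the 75th percentile (0.15) and at the highest background control (0.29), where fewer of its dim members were measured. The arterial median came inside with those floors (0.10 and 0.14), the brightest probe set (0.26), plain probe sets (0.33) and without the farthest member (0.33). The smooth muscle median came inside with no floor (0.23), the brightest probe set (0.15), plain probe sets (0.047) and unmatched lists (0.23). The proliferation median came inside with the background control floor (0.24), the brightest probe set (0.12) and plain probe sets (0.17). Lists inside the range moved out of it with no floor: endocardial (1.19), coagulation (0.42), leukocyte adhesion (0.61), extracellular matrix (-0.17) and antioxidant (-0.23). The antioxidant median also did so with quantile normalization (-0.14), the floor at the 75th percentile (-0.20), the background control floor (-0.20) and the brightest probe set (-0.19), and the growth factor median with deposited values (0.18), centred ratios (0.22), loess (0.21), unmatched lists (0.18) and without the farthest member (0.18). The cause was not tested. In all, 199 list medians kept their side of the range, 14 came inside and 14 moved out, and 0 of those apart changed sign.

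Of the values of named genes under scaling and probe set alternatives, 628 moved by less than 0.39, the SD among probe sets of the same gene, and 19 by more. The sign changed for Gja5 (-0.17), Nos3 (0.03) and Ndufaf3 (0.95) with the brightest probe set and for Ndufaf3 (0.20) with plain probe sets, and Cox6a2 (0.99, quantile normalization) and Myc (-0.71, brightest probe set) came under 2-fold. The floor at the 25th percentile was not run, since that percentile is negative (-0.52) and has no logarithm. No paired analysis was possible because each group had 1 array. Signal over background limits the ratios of dim genes: the ratio was a bound, resting on a value at or under the floor, for 84 of the 174 higher and 51 of the 122 lower genes, and the median intensity exceeded the highest background control on both arrays for 39 and 33.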

Other observations

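The tests of RNA end loss and of Lyz2 against the background controls were chosen after the results were seen, as was the floor at the highest background control. The 3 further lists used below were written after the first lists and the largest differences had been seen, but before the values of their own members were.

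The list of further glycolytic and hypoxia-inducible genes had a lower median on the endocardial array. Of its 23 measured genes, 4 were at least 2-fold lower and 0 higher, with a median log2 ratio of -0.42. The lower genes were the hypoxia-inducible mitochondrial protein Higd1a (at least 2.95-fold lower), hexokinase Hk2 (log2 ratio -1.18), aldolase Aldoc (at least 2.15-fold lower) and the pyruvate dehydrogenase kinase Pdk1 (-1.09). The 2 probe sets of Hk2 disagreed, at -1.96 and -0.40. Other glycolytic enzymes lay on the same side, with Aldoa at -0.88, Pkm at -0.64 and Pgk1 at -0.58, while Mxi1 (0.36) lay above 0, as did Tfrc and Egln3 with median intensities under the highest background control on both arrays. Slc2a1 (-1.65), Slc16a3 (-2.17), Vegfa (-1.16), Ak4 (at least 4.01-fold lower) and Ndufa4l2 (at least 15-fold lower), which prompted the list, were left out of it.

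A hypoxic or glycolytic response in the aortic culture is a candidate explanation for these lower values, and the further list met what it predicts: its median was below that of every one of 10000 matched random lists (percentile 0), and at the 0.03rd percentile with the floor at the highest background control. Partial loss of RNA ends in the endocardial sample was argued against, since the largest ratio of 3' to 5' control values, endocardial over aortic, was 1.03. Hypoxia-inducible genes already seen and left out went both ways, with Adm (1.68), Pfkfb4 (1.97) and Plod2 (0.39) higher and P4ha1 (-0.46) lower, so a uniform hypoxic response may not describe the pattern. With 1 culture of each origin, cell origin and culture state cannot be separated, and a difference between the origins stays open and untested.

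Macrophages among the endocardial cells are a candidate explanation for the higher macrophage and leukocyte genes. Of 34 further macrophage genes on the array, 20 were measured, and the rest were at or under the floor on both arrays. The median of the 20, 0.16, lay at the 98.3rd percentile, and the percentile was 91.3 with the floor at the highest background control. Coro1a, Cd80 and Pf4 were above the floor of 635.4 on the endocardial array alone, so their ratios could only be positive. Of the 20, 1 passed 2-fold, Pf4 (at least 2.85-fold higher against the floor of 635.4). Its endocardial intensity, 1811, was just above the highest background control (1743.4). Lysosomal and related transcripts that other cells share gave log2 ratios of 0.89 for Ctsd, 0.76 for Lgals3, 0.01 for Ctsb and -0.18 for Grn. The lysosomal proteases Ctsh (-0.31) and Ctsl (-0.64) were the lowest of the 20. Noise of dim probe sets may also account for part of the pattern. With the floor at the highest background control the first list had 8 measured members and lay at the 94.9th percentile, inside the range, as that explanation predicts. A raised floor also removes dim members and shrinks ratios whose dimmer value lies under it. The fall therefore cannot tell noise from a true difference. In the main values the list exceeded all 10000 lists of equally dim genes. However, all 15 measured members were above the floor on the endocardial array and 5 on the aortic array. A member with 1 kept probe set, above the floor on the endocardial array alone, could only give a positive ratio. Random lists were matched on mean expression and not on this, so that rank cannot tell noise from a true difference either. For Lyz2 itself noise was argued against, with an endocardial intensity 19.3 times the highest background control. That value was known when the check was chosen, and the check does not address whether its 1 kept probe set is paired with the right gene. Expression of these genes by endocardial endothelium itself stays open and untested.

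Fewer fibroblasts among the endocardial cells could account for the lower fibroblast genes. Of 17 further fibroblast genes on the array, 10 were measured, with a median of -0.13 at the 25.5th percentile, which neither meets nor excludes it. Sfrp4, Ddr1 and Penk had median aortic intensities under the floor of 635.4, and Sfrp4 and Penk could therefore only give positive ratios. The percentile was 8.31 without the farthest member and 3.99 with the floor at the highest background control. Noise of dim probe sets was argued against, since with that floor the first list stayed at the 0.04th percentile. It also kept its 17 members and its median of -0.38. Most members were bright on both arrays, so the raised floor could change little and adds little to what their intensities show. The members went both ways, from Dcn (at least 10.9-fold lower) to Postn (log2 ratio 2.98), and 13 of the 17 also stand in other lists. A change in fibroblast number and a change in matrix genes of the cells labelled endothelial therefore cannot be told apart here. A difference between the origins stays open and untested.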
